A study of Mus musculus with 20 samples.

How the data were processed

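RNA from mouse hearts was sequenced after polyA selection on a NovaSeq instrument, per the labels' protocols, which give wild-type C57BL/6 mice of 12 weeks, tissue kept in RNAlater and shipped frozen. The labels put the 20 samples in groups of 5 by sex and by the names Chow and PA. The series text names chow and high-fat diet, so PA was read as the high-fat diet by elimination. The labels do not say that samples come from separate animals, when hearts were taken, how long the diet lasted or which batch a library belonged to.

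The deposited values are whole counts, in 1 file per sample. The submitters' processing notes list Salmon 1.5.1, DESeq2 1.32.0 and the build GRCm39, but the files are not transcript estimates. In 19 files the deposited counts are given for 425461 pieces of exons, and a read that spans several pieces is counted in each. The file of chow male 4 holds counts for 49315 genes instead. Its total is 31686627, against 57805110 to 85794067 in the others, and the sums over pieces exceed the per-gene count by a median of 0.11 log2 units for genes of a single piece and 1.77 for genes of more than 50. That library could not be set on the scale of the rest, so it was left out of the fit, and chow males number 4. The design written before the data were examined had assumed all 20 libraries and 16 residual degrees of freedom, where the fit has 19 and 15.

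Counts per gene were the sums over its pieces. Of 33309 pieces carrying joined gene IDs, 27829 could be given to a single gene, and 5480 shared by several genes were not used, which set aside 1.35% to 1.49% of counts. No source states that reads were counted by strand, so reads of a gene and its antisense partner, such as Xist and Tsix, are not separated here and Tsix is not reported. Symbols came from the GENCODE vM21 annotation of GRCm38, in which 44772 of 48970 genes (91.4%) had the same chromosome, start and end as in the files. Coordinates are therefore given in GRCm38, although the processing notes name GRCm39. Of 49005 genes with pieces, 18069 passed edgeR's expression filter and were tested. Because a read can count several times, totals overstate the number of reads, and precision comes from the spread between libraries.

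The main test was edgeR 4.0.16's quasi-likelihood F-test with TMM normalisation, 1 model over the 4 groups, and Benjamini-Hochberg adjustment over all genes tested, with genes called at an adjusted p under 0.05. Contrasts were diet in females, diet in males, their difference, their mean, and sex on each diet. Of 54 gene lists, 52 with at least 5 tested genes were tested by camera in limma 3.58.1 with a preset correlation of 0.01, with adjustment over the lists per contrast; lists of thymocyte and Y-linked genes were too small. The alternatives for lists were camera with a correlation estimated per list and fry. The PValue of fry tests whether the genes of a list move, on balance, 1 way, and PValue.Mixed whether they change in either direction, and neither compares the list with other genes. With an estimated correlation, the calls that held were PPAR-alpha targets in males and on average, ATF4 and integrated stress response genes on average, and X-linked genes that escape inactivation on chow. Overlap of calls was tested by a one-sided Fisher's exact test.

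The lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Named genes are, per contrast, the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM and an established symbol, up to 4 called members of each list with the smallest p, and fixed exceptions for sex labels, fat supply, cardiac stress, adipose tissue and time of day. Where fewer than 5 genes were called, the 5 with the smallest p are named. Of the genes that this rule names, 1 is not reported here. A zero level is read against a floor of 3 counts.

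Alternatives were DESeq2 1.42.0, its median-ratio size factors in edgeR, no filter, a stricter filter of 1 CPM in 5 libraries, only the groups compared, a replicate block, and each library left out in turn. The alternatives chosen after the data were seen were leaving out high-fat females 4 and 5, a GC covariate per library, the largest exon piece of each gene, and the per-gene library joined as it stands. A transcript-length offset was planned for transcript estimates and was not run, since the files hold none.

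The scripts were tested on simulated counts with 200 changed genes. At a fold of 2 the test recovered 73.1% of changed genes for diet in females, 77.6% for diet in males, 53.7% for the interaction, 61.2% for sex on chow, 58.2% for sex on high fat and 74.6% for the average; at a fold of 1.5 it recovered 26.9% for the interaction. Between 2 and 8 unchanged genes were called per contrast. All groups were drawn with the same spread for a gene, and no library departed from the rest. These rates may therefore not hold where groups differ in spread or libraries depart, as in the high-fat females. A list raised by 1.5 was called, and of 51 other lists 4 were called, 0 of them without shared members. Genes were drawn independently in that simulation, so it cannot show how often correlation between the genes of a list gives false list calls. A loss of 0.5 put in along the gene moved the 5′ to 3′ ratio by -0.353 against 0.0091 in an unchanged library. A GC slope of 0.5 put on genes gave 0.485 between genes and 0.0018 within them, and the same slope put on pieces gave 0.401 and 0.401. Other tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

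Chance between the samples was checked by other splits of the libraries, at most 100 per contrast. No same-group pair of libraries differed by as little as counting noise: in the largest exon piece of each gene, where a read counts once, the chi-square per gene of the 36 pairs ran from 3.16 to 144, and copies would give about 1. For the sums over pieces it ran from 8.17 to 357, where copies give more than 1 because reads are counted several times.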

Results

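Messenger RNA was sequenced from hearts of 12-week-old wild-type C57BL/6 mice of both sexes kept on chow or on a high-fat diet, with 20 samples in 4 groups of 5. The libraries named PA were read as the high-fat groups, since the series names only chow and high-fat diet and the remaining libraries are named chow. Chow male 4 was counted in another way and is left out of the comparisons, which leaves 5 chow females, 4 chow males, 5 high-fat females and 5 high-fat males. The 19 libraries compared held 57805110 to 85794067 counts each, and 22202 to 24694 genes had a count in a library. Levels are given as CPM, counts scaled to the TMM-adjusted library size, with the SD between libraries, and 3 counts, the floor used for a gene not seen, are worth 0.0526 CPM in the smallest library. That floor covers counting error only. The labels do not say that each library comes from a separate animal, so the p-values measure the spread between these samples.

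The sex-linked genes matched the labels in every library. Xist, the RNA that silences 1 X chromosome in females, stood at 128 ± 11.4 CPM in chow females, 0.270 in chow males and 0.514 in high-fat males. Kdm5d, a gene of the Y chromosome, had no count in any female library and stood at 18.97 ± 0.79 CPM in chow males and 20.8 ± 1.85 CPM in high-fat males. Ddx3y stood at 78.1 and 89.0 CPM in chow and high-fat males, Eif2s3y at 73.2 and 72.4 CPM, and Uty at 31.6 and 32.6 CPM. In high-fat females Xist averaged 86.9 ± 66.7 CPM, with 18.0 and 10.7 CPM in females 4 and 5 of that group.

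High-fat females 4 and 5 stood apart from all other libraries. On the axis of largest variation, which held 46.1% of the variance, they lay at 95.02 and 131.9, against -20.9 to -1.89 for the other 17 libraries. Their levels rose with the GC content of a gene by 0.57 and 0.85 log2 units per 10 percentage points, against -0.07 to 0.13 elsewhere. Malat1, a long RNA kept in the nucleus, stood at 117 and 63.9 CPM in them and at 1132 to 1533 CPM in the other libraries. The number of genes called in each comparison is therefore also given without these 2 libraries. That choice was made after the data had been seen. Some of the counts in gene lists are given in the same way.

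**Figure D1:**
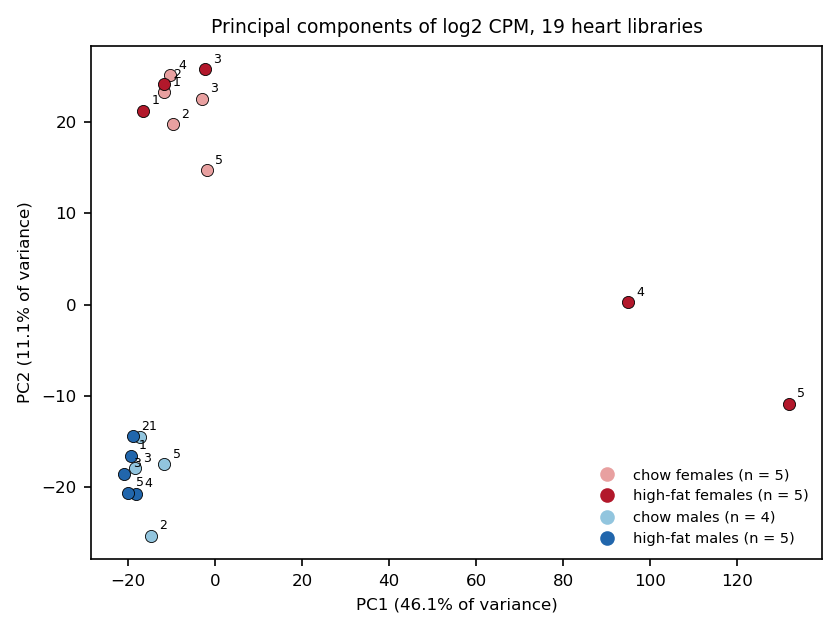
The positions of the 19 libraries on the axes of largest and next largest variation of log2 CPM are plotted, 1 numbered point per library, coloured by group. High-fat females 4 and 5 lie at 95.02 and 131.9 on the horizontal axis, and all other libraries lie between -20.9 and -1.89.

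**Figure D2:**
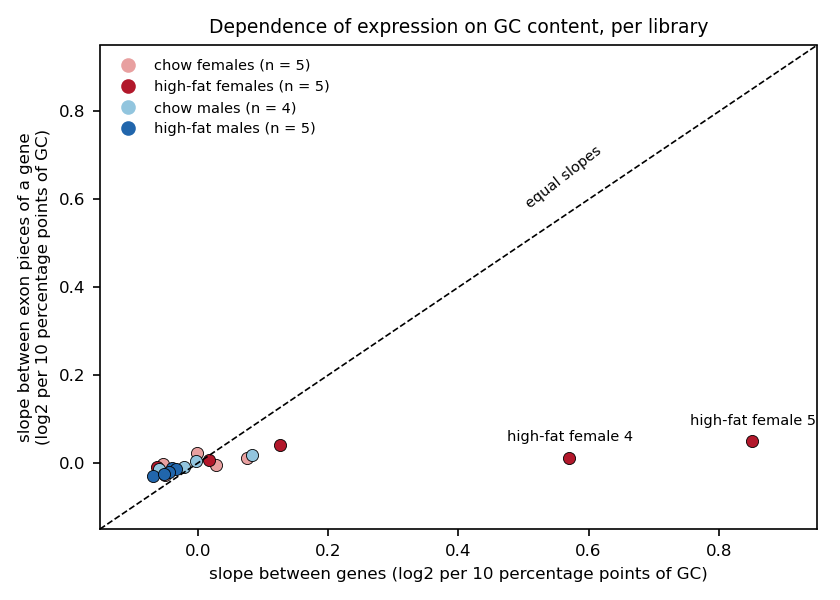
For each of the 19 libraries, coloured by group, the horizontal axis gives the slope of log2 level on GC content between genes and the vertical axis that between exon pieces of the same gene, both per 10 percentage points; the dashed line marks equal slopes. High-fat females 4 and 5 have slopes of 0.57 and 0.85 between genes and of 0.01 and 0.05 between pieces of a gene.

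The comparison of high-fat with chow females asks what the diet changed in the female heart. Members of the lists for fatty acid use, the amino acid stress response and the extracellular matrix were called higher, though none of these list calls held with an estimated correlation. Single genes of glucose uptake and ketone body use were called lower. Pdk4, a kinase that restrains pyruvate dehydrogenase, rose from 318 ± 81.3 to 866 ± 177 CPM (SD, n = 5 and 5), and Cyp1a1, a cytochrome P450 of xenobiotic metabolism, rose from 0.264 ± 0.0908 to 1.74 ± 0.42 CPM. Slc2a1, the glucose transporter GLUT1, fell from 23.7 ± 2.41 to 15.7 ± 2.11 CPM. In each of these genes all 5 high-fat females lay beyond every chow female.

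In these females edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 457 of 18069 genes, 301 higher and 156 lower on the high-fat diet. Without females 4 and 5 it called 906 genes, 449 higher and 457 lower, and 319 genes were called in both fits. Both fits took their spread from all 4 groups. A fit to the female libraries alone called 21 genes, 13 higher and 8 lower, all of them among the 457. Single libraries moved the count for diet in females to 252 without chow female 1, 219 without chow female 4, 278 without high-fat female 4 and 909 without high-fat female 1. Large rises by that test were measured in Cyp1a1 (log2 change 2.70 ± 0.23 SE, adjusted p = 1.65e-05), Chrna2, a nicotinic receptor subunit (1.84 ± 0.25, adjusted p = 0.00108), and Mthfd2, a mitochondrial enzyme of folate metabolism (1.52 ± 0.20, adjusted p = 0.000993). Pdk4 rose by 1.45 ± 0.17 and Scn4b, a sodium channel subunit, by 0.74 ± 0.10. Falls that held with each single library left out included Abat, which breaks down GABA (-1.30 ± 0.16), Gnb3 (-1.23 ± 0.20), and Scgb1c1 (-1.12 ± 0.17), with adjusted p by edgeR's quasi-likelihood test from 0.000666 to 0.00432. Oxct1, the enzyme that lets tissue burn ketone bodies, fell by 0.36 with an SE of 0.05. In each of these genes all 5 high-fat females lay beyond every chow female, and no single library left out ended a call. Nppa, the atrial natriuretic peptide, stood at 124 ± 23.6 CPM on chow and 61.7 ± 18.8 CPM on high fat, a fall whose call (edgeR adjusted p = 0.0266) ended without chow female 1, chow female 4 or high-fat female 3.

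Among the gene lists fixed before the data were examined, 12 of 28 PPAR-alpha target genes rose in females and none fell, and 22 rose when adjusted over the list alone (camera adjusted p = 6.96e-25; adjusted p = 0.053 with an estimated correlation). Acot1 and Acot2, thioesterases of fatty acyl-CoA, rose by 1.33 ± 0.23 and 0.96 ± 0.14, and without females 4 and 5 the count of called targets was 6. Of 19 genes of mitochondrial fatty acid oxidation 6 rose, Decr1 by 0.48 ± 0.08 and Hadha by 0.37 ± 0.07, and 14 rose and 1 fell when adjusted over the list alone (camera adjusted p = 2.36e-09; adjusted p = 0.371 with an estimated correlation), and without females 4 and 5 the count was 3 higher and 1 lower. The median change of that list was 0.45 and 0.50 in females 4 and 5 against 0.10, 0.09 and 0.09 in females 1, 2 and 3. Of 22 ATF4 and integrated stress response genes 4 rose, among them Mthfd2, Psat1 of serine synthesis (0.80 ± 0.13), Asns, the asparagine synthetase (0.73 ± 0.11), and Atf5 (0.45 ± 0.08), and 7 rose and 1 fell when adjusted over the list alone (camera adjusted p = 2e-07; adjusted p = 0.053 with an estimated correlation).

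Of 36 extracellular matrix genes 13 rose and none fell, and 20 rose and 1 fell when adjusted over the list alone (camera adjusted p = 4.95e-14; adjusted p = 0.0693 with an estimated correlation). Col1a1, a chain of type I collagen, rose from 138 ± 6.91 to 195 ± 18.0 CPM, Col3a1 rose by 0.52 ± 0.08 and the cross-linking enzyme Loxl1 by 0.46 ± 0.06, each in 5 of 5 libraries beyond every chow female. Of 22 fibroblast markers 4 rose (camera adjusted p = 6.53e-12; adjusted p = 0.053 with an estimated correlation) and of 23 endothelial markers 5 rose, among them Cdh5 by 0.29 ± 0.05 (camera adjusted p = 6.42e-06; adjusted p = 0.053 with an estimated correlation). Of 34 cell cycle genes 1 rose, with a median change of 0.48 (camera adjusted p = 1.65e-05; adjusted p = 0.648 with an estimated correlation). Without females 4 and 5 that count was 22, with a median of 0.85 (camera adjusted p = 5.89e-27; adjusted p = 0.0412 with an estimated correlation). Of 14 erythroid and blood markers 1 rose, with a median of 0.38 (camera adjusted p = 8.92e-05; adjusted p = 0.153 with an estimated correlation). For these markers the count without females 4 and 5 was 7, with a median of 0.56 (camera adjusted p = 2.21e-08; adjusted p = 0.0412 with an estimated correlation). Genes that break down branched-chain amino acids had a median of -0.14, with 1 of 23 called lower (camera adjusted p = 0.00279; adjusted p = 0.371 with an estimated correlation). Of these genes 14 were called lower without females 4 and 5 (camera adjusted p = 1.78e-16; adjusted p = 0.0412 with an estimated correlation). Of 37 nuclear-encoded genes of complex I none was called, with a median of -0.02 (camera adjusted p = 0.703; adjusted p = 0.949 with an estimated correlation). Without females 4 and 5 there were 13 called lower (list by camera adjusted p = 2.43e-19; adjusted p = 0.182 with an estimated correlation). In all, 19 of 52 lists were called in females by camera, 17 higher and 2 lower, and none of these calls held with an estimated correlation.

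**Figure D3:**
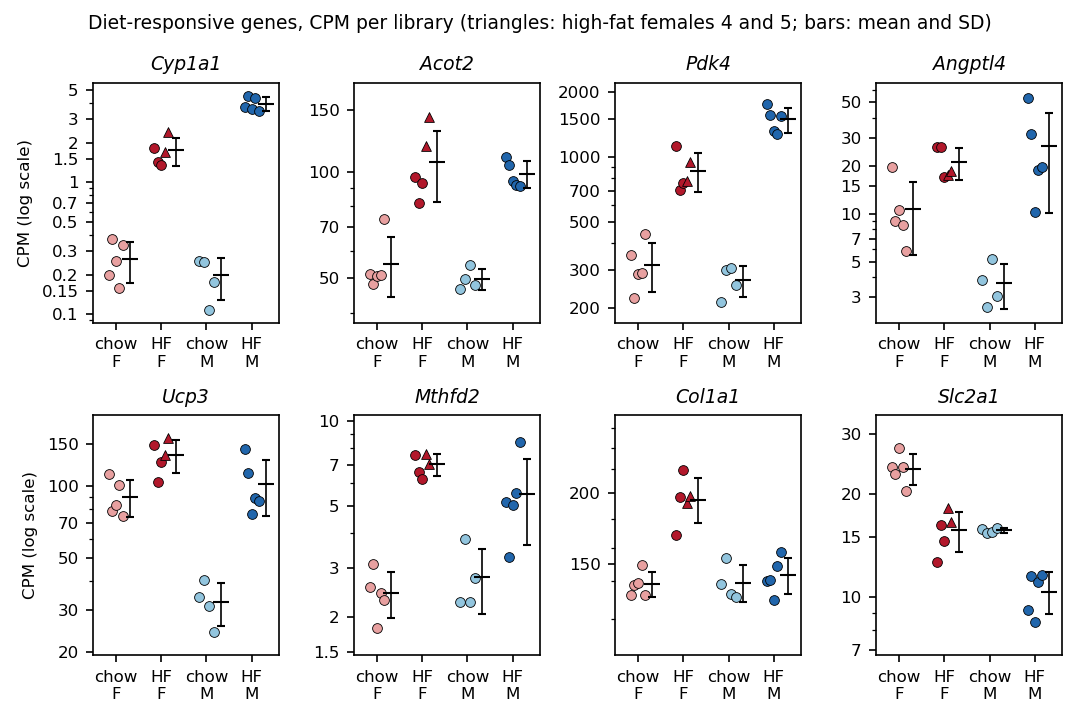
The level of 8 diet-responsive genes in CPM, on log axes, is plotted for each library of the 4 groups, with the group mean and SD as a bar beside the points; triangles are high-fat females 4 and 5. Pdk4 averages 318 and 866 CPM in chow and high-fat females and 269 and 1499 CPM in chow and high-fat males, and Col1a1 averages 138 and 195 CPM in females and 139 and 143 CPM in males.

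The same comparison in males asks what the diet changed in the male heart. Members of the lists for fatty acid use were called higher there as well, and members of those for protein folding in the endoplasmic reticulum and for glycolysis lower. Of these list calls only that of PPAR-alpha targets held with an estimated correlation. Pdk4 rose from 269 ± 43.2 to 1499 ± 200 CPM (SD, n = 4 and 5), and Cyp1a1 from 0.198 ± 0.0696 to 3.93 ± 0.469 CPM. Angptl4, a secreted inhibitor of lipoprotein lipase, rose from 3.69 ± 1.15 to 26.6 ± 16.5 CPM, and Ucp3, a mitochondrial carrier of the uncoupling family, from 32.5 ± 6.66 to 102 ± 27.0 CPM. In each of these genes all 5 high-fat males lay above every chow male.

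By edgeR's quasi-likelihood test 138 genes were called in males, 72 higher and 66 lower. In the fit without high-fat females 4 and 5, which also sets the shared spread, the count was 474, with 249 higher and 225 lower, and all 138 were among them. Single libraries moved the count for diet in males to 42, 47, 83 and 52 without chow male 1, 2, 3 and 5, and to 80, 74 and 79 without high-fat male 2, 3 and 5. The log2 changes were 4.31 ± 0.27 (SE) for Cyp1a1, 2.85 ± 0.43 for Angptl4, 2.48 ± 0.19 for Pdk4 and 1.65 ± 0.19 for Ucp3, with adjusted p by edgeR's quasi-likelihood test from 6.92e-08 to 0.00242. Gpam, an enzyme of triglyceride synthesis, rose by 0.69 ± 0.08 and Lipe, the hormone-sensitive lipase, by 0.68 ± 0.10. Falls with 5 of 5 libraries below every chow male were measured for Scgb1c1 (-1.36 ± 0.18), Lgi3 (-1.21 ± 0.16), Abat (-1.14 ± 0.17) and Oxct1 (-0.37 ± 0.05), with adjusted p by edgeR's quasi-likelihood test from 0.000993 to 0.00222. Slc2a1 fell from 15.7 ± 0.217 to 10.4 ± 1.44 CPM, a call (edgeR adjusted p = 0.0139) that ended without chow male 1.

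Of the 28 PPAR-alpha targets 16 rose in males and none fell, and 24 rose when adjusted over the list alone (camera adjusted p = 2.96e-67). That call also held with an estimated correlation (adjusted p = 0.00239), and none of the other list calls in males did. In the fit without high-fat females 4 and 5 the targets called numbered 24. Of 19 genes of mitochondrial fatty acid oxidation 6 rose, with a median of 0.25 (camera adjusted p = 6.51e-16; adjusted p = 0.208 with an estimated correlation), and 14 rose in that fit. Of 26 genes of fatty acid uptake and lipid droplets 4 rose, with Fabp4 higher by 0.38 ± 0.07, a call that ended without chow male 2 (list by camera adjusted p = 4.08e-06; adjusted p = 0.209 with an estimated correlation), and 9 rose and 2 fell in that fit. Of 23 genes of the unfolded protein response 3 fell and none rose, and 12 fell and 1 rose when adjusted over the list alone (camera adjusted p = 3.13e-13; adjusted p = 0.129 with an estimated correlation), and 6 fell in that fit. Syvn1, a ubiquitin ligase that clears misfolded proteins, fell by 0.44 with an SE of 0.06. Of 25 genes of glucose uptake and glycolysis 4 fell (camera adjusted p = 1.28e-07; adjusted p = 0.282 with an estimated correlation), and 8 in that fit. White adipocyte markers were called higher too, with 3 of 17 genes and a median of 0.002 (camera adjusted p = 0.000244, and adjusted p = 0.203 with an estimated correlation). In all, 20 lists were called in males by camera, 11 higher and 9 lower.

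**Figure D4:**
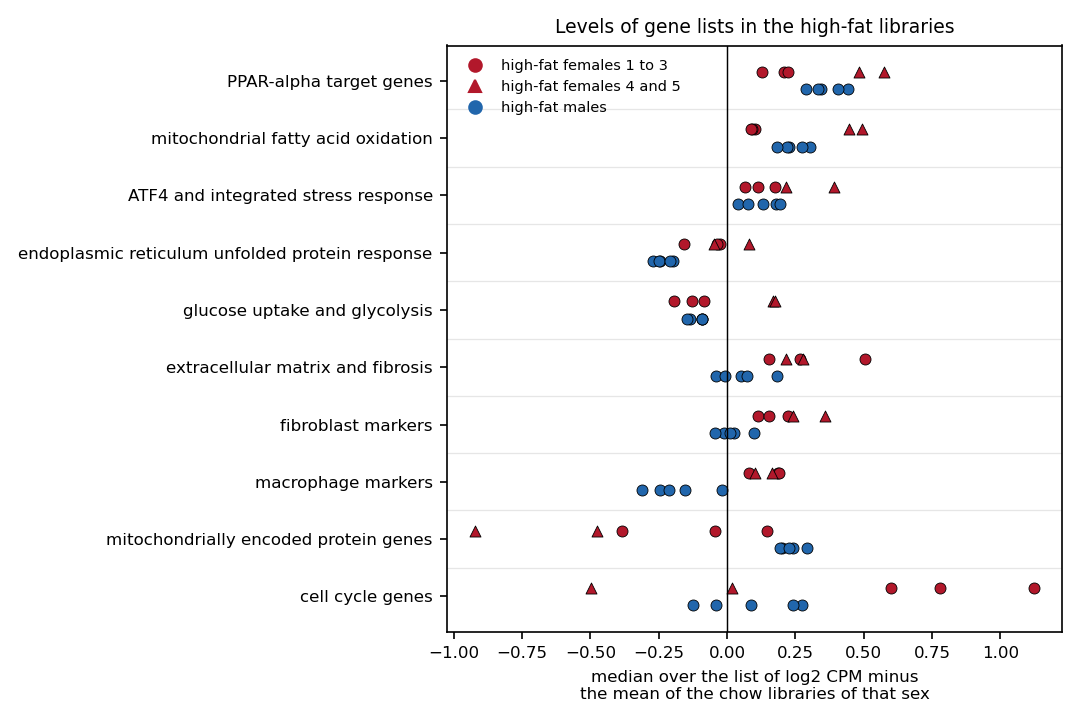
For each of the 10 high-fat libraries, 1 point per library, the horizontal axis gives the median over a gene list of log2 CPM minus the mean of the chow libraries of that sex, for 10 lists; triangles are high-fat females 4 and 5. PPAR-alpha targets lie at 0.127 to 0.574 in the 5 high-fat females, and mitochondrially encoded genes lie at -0.92 to 0.15 in the same libraries.

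The 2 sexes shared diet-responsive genes. Called in both were 32 genes higher on high fat, where independent lists give 1.2 (Fisher's exact test, one-sided p = 3.67e-38), and 24 lower, where they give 0.57 (p = 2.15e-33 by the same exact test); no gene was called in opposite directions. The exact test treats genes as independent, and both contrasts take a gene's spread from the same fit. These p-values and the numbers given for independent lists are therefore only a guide. The shared rises included Cyp1a1, Pdk4, Mthfd2, Acot2, Chrna2, Scn4b, Decr1 and Gpam, and the shared falls included Abat, Scgb1c1, Slc2a1 and Oxct1. Without high-fat females 4 and 5 the count was 58 higher and 94 lower in both, with 1 gene called in opposite directions. Single libraries moved the overlap of diet calls between sexes from 56 to 20, 29, 33 and 27 without chow male 1, 2, 3 and 5, and to 37 without high-fat male 3. Across all genes, which are not independent replicates, the log2 changes of the 2 sexes had r = 0.072 and rho = 0.016, and r = 0.161 and rho = 0.215 without those libraries. Over the 13512 genes with a mean of at least 1 CPM they had r = 0.087 and rho = 0.005, and r = 0.305 and rho = 0.312 without those libraries.

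The interaction of diet and sex asks whether the diet acted differently in females and males. The effect on Pdk4 was 1.45 in females and 2.48 in males, that on Ucp3 0.58 and 1.65, and that on Angptl4 0.97 and 2.85 log2 units. These differences (-1.03 ± 0.24, -1.07 ± 0.25 and -1.88 ± 0.54) did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.207, 0.215 and 0.31). By that test 0 genes were called, with or without high-fat females 4 and 5, against 1839 with an unadjusted p under 0.05, and DESeq2 called 60. Without high-fat female 1 edgeR called 5 for the diet by sex interaction. The genes with the smallest p were Ankrd13a, Mid1ip1, Sirpa and Syvn1, none of which passed (edgeR adjusted p = 0.0952 each), and Cited4 (edgeR adjusted p = 0.105). Of the lists 13 were called by camera, none of them with an estimated correlation. The fibroblast list had a median interaction of 0.20 and the extracellular matrix list of 0.25, with higher diet effects in females (camera adjusted p = 2.27e-08 and 1.12e-06; adjusted p = 0.405 and 0.639 with an estimated correlation). The mitochondrially encoded genes had a median of -0.49 (camera adjusted p = 6.33e-08; adjusted p = 0.639 with an estimated correlation). These genes lay at 0.15, -0.04, -0.38, -0.48 and -0.92 against chow females in high-fat females 1 to 5, and without females 4 and 5 the median interaction was -0.30 (camera adjusted p = 1.13e-08; adjusted p = 0.246 with an estimated correlation).

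The comparison of chow females with chow males asks how the hearts differed by sex without the diet. Genes of the circadian clock lay far apart between the sexes. Dbp, a clock output factor, stood at 91.8 ± 13.8 CPM in chow females and 8.95 ± 1.498 CPM in chow males (SD, n = 5 and 4), and Arntl, the clock activator also called Bmal1, at 11.8 ± 2.37 and 37.6 ± 2.19 CPM. Of 19 clock genes 9 were higher and 5 lower in females, and 12 and 5 when adjusted over the list alone. Per3 (1.61 ± 0.19) and Nr1d1 (1.24 ± 0.11) lay on the side of Dbp (3.36 ± 0.21), and Cry1 (-0.97 ± 0.08) on that of Arntl (-1.67 ± 0.15). For these genes the adjusted p by edgeR's quasi-likelihood test ran from 1.41e-08 to 6.3e-05, and all 5 females lay beyond every male. The test of the list's members in either direction gave an adjusted p of 1.44e-10 (fry, mixed), and that in one direction by camera an adjusted p = 0.000631 (adjusted p = 0.209 with an estimated correlation). The labels give no time of day at which hearts were taken.

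In all, edgeR's quasi-likelihood test called 582 genes between the sexes on chow, 313 higher and 269 lower in females. Without high-fat females 4 and 5, which changes the shared spread, it called 1916, with 917 higher and 999 lower, and all 582 were among them. Beyond the clock, Ucp3 (1.47 ± 0.19), Cth, an enzyme of cysteine synthesis (1.54 ± 0.15), Tcap, a protein of the sarcomere's Z-disc (1.42 ± 0.16), and the fibril-associated collagen Col14a1 (1.07 ± 0.13) were higher in females. The complement gene C7 (-2.47 ± 0.18), the peptidase gene Lvrn (-2.28 ± 0.36), the interferon-inducible gene Ifi205 (-1.97 ± 0.31) and the elastin gene Eln (-0.83 ± 0.14) were lower. For these genes the adjusted p by edgeR's quasi-likelihood test ran from 1.95e-07 to 0.00335, and 5 of 5 females lay beyond every male. Of 10 X-linked genes that escape inactivation 4 were higher in females, with Eif2s3x by 0.71 ± 0.06 and Kdm5c by 0.48 ± 0.04, and the list held with an estimated correlation (camera adjusted p = 1.01e-14; adjusted p = 0.0212 with an estimated correlation). Of 23 genes of the unfolded protein response 2 were lower, among them Syvn1 (-0.47 ± 0.06), and 9 were lower when adjusted over the list alone (camera adjusted p = 0.000193; adjusted p = 0.586 with an estimated correlation). Single libraries moved the count for sex on chow to 378 and 356 without chow female 1 and 4, and to 348, 259 and 307 without chow male 1, 2 and 3.

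**Figure D5:**
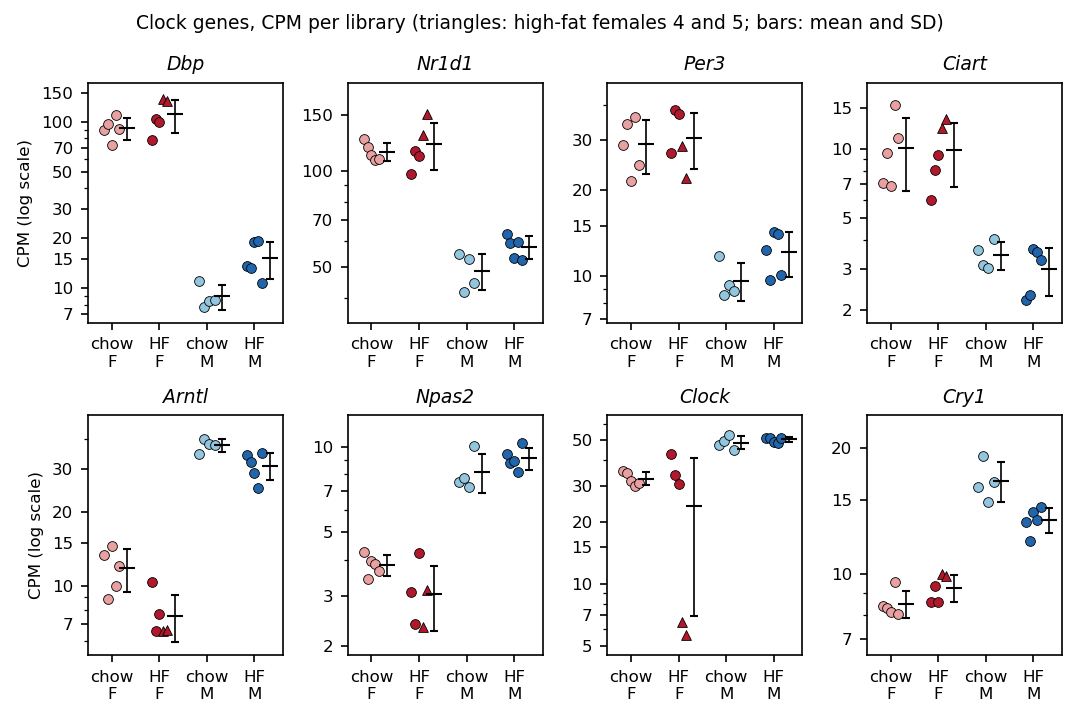
The level of 8 clock genes in CPM, on log axes, is plotted for each library of the 4 groups, with the group mean and SD as a bar beside the points; triangles are high-fat females 4 and 5. Dbp averages 91.8 and 111 CPM in chow and high-fat females and 8.95 and 15.2 CPM in chow and high-fat males, and Arntl averages 11.8, 7.56, 37.6 and 31.1 CPM in the same order.

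The comparison of the sexes on the high-fat diet asks which of these differences were present under the diet. Clock genes again lay apart, with 10 of 19 higher and 5 lower in females (camera adjusted p = 0.00406; adjusted p = 0.28 with an estimated correlation). Dbp stood at 111 ± 24.7 CPM in high-fat females and 15.2 ± 3.79 CPM in high-fat males, and Arntl at 7.56 ± 1.66 and 31.1 ± 4.05 CPM (SD, n = 5 and 5). Matrix and fibroblast genes were higher in females: 12 of 22 fibroblast markers, with 15 higher and 1 lower when adjusted over the list alone (camera adjusted p = 2.19e-09; adjusted p = 0.28 with an estimated correlation), and 16 of 36 matrix genes, with 2 lower (camera adjusted p = 5.75e-06; adjusted p = 0.58 with an estimated correlation). Col14a1 (1.44 ± 0.12), the secreted Dkk3 (1.81 ± 0.16), Col1a1 (0.44 ± 0.07) and Lum, a proteoglycan of collagen fibrils (0.60 ± 0.09), were among them. Pdk4 (-0.79 ± 0.17) and Cd36, a fatty acid transporter (-0.40 ± 0.08), were lower in females. For these genes the adjusted p by edgeR's quasi-likelihood test ran from 9e-07 to 0.00677, and all 5 females lay beyond every male.

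Between the sexes on high fat edgeR's quasi-likelihood test called 1866 genes, 1157 higher and 709 lower in females. Without females 4 and 5 it called 1896, 895 higher and 1001 lower, and 1100 genes were called in both. A fit to the high-fat libraries alone called 547 genes, 357 higher and 190 lower. Single libraries moved the count for sex on high-fat diet to 3447 and 1110 without high-fat female 1 and 4, and to 1096, 1181 and 1222 without high-fat male 3, 4 and 5. Of 13 mitochondrially encoded genes 7 were lower in females, mt-Nd1 by -0.44 ± 0.09 (camera adjusted p = 1.99e-08; adjusted p = 0.49 with an estimated correlation), and 9 were lower without females 4 and 5. Of 81 cytosolic ribosomal protein genes 17 were higher, and 64 when adjusted over the list alone (camera adjusted p = 1.16e-12; adjusted p = 0.816 with an estimated correlation), and 1 was higher without females 4 and 5. Of 34 cell cycle genes 5 were higher, among them Mcm5 (0.79 ± 0.14) and Mcm6 (0.44 ± 0.09) (list by camera adjusted p = 0.00528; adjusted p = 0.883 with an estimated correlation). Without females 4 and 5 that count was 22 (camera adjusted p = 3.96e-17; adjusted p = 0.147 with an estimated correlation). C7 (-2.14 ± 0.17), Lvrn (-2.83 ± 0.36) and Ifi205 (-2.50 ± 0.31) were lower in females, as on chow, in 5 of 5 libraries.

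The diet effect averaged over the sexes asks which genes changed with the diet on average. A gene that responds in females alone or in males alone can be called, so a call does not show a general change. When females and males were tested apart, 56 genes were called the same way in both. For the average, edgeR's quasi-likelihood test called 530 genes, 313 higher and 217 lower. Without high-fat females 4 and 5 the count was 1549, with 707 higher and 842 lower, and 526 of the 530 were among them. PPAR-alpha targets rose in 24 of 28 cases (camera adjusted p = 8.69e-69) and ATF4 and integrated stress response genes in 5 of 22 (camera adjusted p = 3.99e-09), and both lists held with an estimated correlation (adjusted p = 0.00222 and 0.0435). Without high-fat females 4 and 5 the call with an estimated correlation held for PPAR-alpha targets (camera adjusted p = 0.012) and was lost for ATF4 and integrated stress response genes (camera adjusted p = 0.0582). Of 19 genes of mitochondrial fatty acid oxidation 12 rose (camera adjusted p = 1.07e-19; adjusted p = 0.0969 with an estimated correlation), with Cpt1a, which admits long-chain fatty acids to mitochondria, up by 0.40 ± 0.06. Of 23 unfolded protein response genes 4 fell, Hspa5, the chaperone BiP, by 0.48 with an SE of 0.09 (list by camera adjusted p = 3.27e-07; adjusted p = 0.146 with an estimated correlation). Of 25 genes of glucose uptake and glycolysis 4 fell, among them Slc2a1 (-0.60 ± 0.07) and the insulin-responsive transporter Slc2a4 (-0.32 ± 0.05) (list by camera adjusted p = 0.000277; adjusted p = 0.484 with an estimated correlation). The fall was called in 12 of them without high-fat females 4 and 5 (list by camera adjusted p = 8.82e-16; adjusted p = 0.0456 with an estimated correlation). Nppa was lower by -0.89 ± 0.17, while Myh7 (-0.20 ± 0.09), Nppb (-0.54 ± 0.15), Acta1 (0.19 ± 0.16) and Adipoq (0.20 ± 0.50) did not pass the test (edgeR adjusted p = 0.276, 0.0586, 0.647 and 0.89).

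Positions of some of the leading genes are given in the mouse build GRCm38, as in the files. Cyp1a1 (ENSMUSG00000032315) is on chromosome 9 from 57687928 to 57703824, and Pdk4 (ENSMUSG00000019577) on chromosome 6 from 5483351 to 5496309. Abat (ENSMUSG00000057880) is on chromosome 16 from 8513429 to 8621568, Dbp (ENSMUSG00000059824) on chromosome 7 from 45705088 to 45710203, and Arntl (ENSMUSG00000055116) on the same chromosome from 113207465 to 113314126.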

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

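The tests of explanations below and the other splits of the libraries for diet in females and diet in males were chosen after the results were seen, whereas the remaining splits were set before their results were seen.

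High-fat females 4 and 5 stood far from all other libraries, at 95.02 and 131.9 on an axis where the others lay between -20.9 and -1.89. RNA broken before polyA selection predicts a loss of 5′ ends in both, but the lower of their 5′ to 3′ ratios was -0.1404 and the other libraries ran from -0.2013 to 0.047, which argues against it. GC bias on fragments predicts that pieces within a gene follow GC as genes do. The slope within genes was at most 0.0583 of the slope between genes, which argues against a bias set by the GC content of each piece. A read can count in several pieces, which the simulation did not model. The ratio that a bias on whole fragments would give is therefore not known, and such a bias is not excluded. Loss of RNA kept in the nucleus may account for part, since 11 listed nuclear RNAs lay at a median of -1.42 and -1.74 against mRNAs of like GC content (other females -0.04 to 0.09), but some of these RNAs had been seen before the list was written. Over 1041 long non-coding RNAs, a test chosen after that list had been measured, the medians were -0.0512 and -0.0648 (other females -0.0117 to 0.0171), below the range but small, so this stays open, and no biological explanation was tested.

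Clock genes differed between the sexes on both diets. High-fat females 4 and 5 are in neither chow group and enter the comparison on chow only through the shared fit. Their departure from the other libraries is therefore a question for the comparison on high fat. Without those libraries 16 of 19 clock genes were called the same way on both diets, which argues against them as the source there. Collection of the sexes at different times of day may give this picture: the median sex difference of genes on the side of Dbp and Per lay above that of genes on the side of Arntl by 2.204 log2 units on chow and by 2.343 on high fat. A sex difference in the phase of the clock gives the same gap, and no label gives a time of day, so these cannot be told apart here.

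Cell cycle genes were called in high-fat females mainly without libraries 4 and 5, with 22 of 34 higher against 1 of 34 with them. A loss that follows GC content and hides a rise in those libraries predicts that their cell cycle genes lie above mRNAs of like GC content as in high-fat females 1, 2 and 3, which had medians of 0.437 to 0.778. The medians were 0.097 and -0.17 in females 4 and 5, no higher than the highest chow female (0.152), which argues against it. Blood left in the hearts may be the source of the rise. Haemoglobin RNA stood at 346.4 to 404.7 CPM in females 1, 2 and 3, with cell cycle levels of 0.599 to 1.123, and libraries of other groups with as much of it reached a cell cycle level of at most 0.274 (high-fat male 3, 402.6 CPM). In those libraries, however, the erythroid list lay at 0.278 and 0.22, below the 0.482 to 0.701 of females 1, 2 and 3, so they do not match in other blood RNA. High-fat female 5 matches on the erythroid list (0.49) with a cell cycle level of -0.496, which goes against blood, but it is a single library that departs from the rest, so both blood and an effect of the diet on dividing cells in females stay open.

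Other splits of the libraries argue against chance for most counts of called genes. With at most 100 splits a share under 1 of 100 could not be seen, so chance is not excluded. For diet in females 2 of 100 splits, the real one included, gave as many as the 457 genes, and the highest other, 1196, exchanged chow females 1 and 2 with high-fat females 4 and 5, which points to a structure of the samples. Without high-fat females 4 and 5, and again counting the real one, as in all counts that follow, 1 of 56 splits reached the 906 genes, with 755 as the highest other. That split set chow females 3, 4 and 5 against chow females 1 and 2 with high-fat females 1, 2 and 3, and the split with 1196 genes parted the same chow females. The 5′ to 3′ ratio was -0.2013 to -0.1699 in chow females 3, 4 and 5 and -0.0339 and 0.0287 in chow females 1 and 2, so a structure lies within the chow females, and its share in the counts for diet in females was not tested. For diet in males 1 of 100 splits reached the 138 genes (highest other 4), and without high-fat females 4 and 5 1 of 100 reached 474 (highest other 50). For sex on chow 1 of 100 reached 582 (highest other 65), for sex on high fat 1 of 100 reached 1866 (highest other 4), and for the average of the diet effects 1 of 100 reached 530 (highest other 1). For the interaction edgeR called 0 genes, which every split reaches (100 of 100, highest other 3), so this comparison says nothing about chance there.

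Of 86 sets of library values examined for a single far value, 3 held one, where chance gives about 1 in 20, or 4.3. Eif2s3y stood at 61.82 CPM in chow male 5, below the other chow males. Uty stood at 0.1867 CPM in chow female 5 and at 0.01513 CPM in high-fat female 3, where the other high-fat females had no count.

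The diet effect differed between the sexes for 13 gene lists by the interaction in camera, none with an estimated correlation. Effects carry their sign, so a higher effect in females can come from a larger fall in males. Glycolysis had a median change of -0.004 in females and -0.13 in males, and the unfolded protein response of -0.072 and -0.224. Higher diet effects in females than in males were measured for fatty acid synthesis (median 0.09, adjusted p = 0.0437; with an estimated correlation adjusted p = 0.697), glycolysis (0.13, adjusted p = 0.0267; 0.984), extracellular matrix (0.25, adjusted p = 1.12e-06; 0.639), the unfolded protein response (0.12, adjusted p = 0.00355; 0.757) and macrophage markers (0.30, adjusted p = 4.74e-06; 0.639). The same direction was measured for endothelial markers (0.11, adjusted p = 0.0437; with an estimated correlation adjusted p = 0.697), fibroblast markers (0.20, adjusted p = 2.27e-08; 0.405), erythroid markers (0.22, adjusted p = 0.0276; 0.697), cell cycle genes (0.39, adjusted p = 0.0251; 0.997) and ribosomal proteins (0.05, adjusted p = 0.0437; 0.997). Lower effects in females were measured for PPAR-alpha targets (-0.07, adjusted p = 0.0437; with an estimated correlation adjusted p = 0.997), mitochondrially encoded genes (-0.49, adjusted p = 6.33e-08; 0.639) and glucocorticoid-responsive genes (-0.25, adjusted p = 0.0119; 0.757). Without high-fat females 4 and 5 camera no longer called fatty acid synthesis (adjusted p = 0.379), glycolysis turned without a call (median -0.01, adjusted p = 0.69) and ribosomal proteins turned to lower effects in females (median -0.08, adjusted p = 4.81e-05; with an estimated correlation adjusted p = 0.67). The medians grew in that fit for PPAR-alpha targets (-0.18, camera adjusted p = 3.99e-11), glucocorticoid-responsive genes (-0.42, adjusted p = 1.12e-06), erythroid markers (0.38, adjusted p = 6.35e-05) and cell cycle genes (0.82, adjusted p = 1.44e-18), and shrank for mitochondrially encoded genes (-0.30, adjusted p = 1.13e-08). None of these calls held with an estimated correlation in that fit (camera adjusted p = 0.204 for cell cycle genes and 0.246 for each of the other 4 lists).

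Chow male 4, which entered none of the comparisons above, held 6084 counts of Y-linked genes (Ddx3y 3013, Eif2s3y 1772, Uty 748 and Kdm5d 551) and 14 of Xist.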

How the results depend on the processing

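Leaving out high-fat females 4 and 5, the GC covariate, the largest exon piece and the per-gene library are alternatives chosen after the data were seen. No named gene whose change was called turned its direction under any alternative. Of the values of named genes with 1 library left out, 8615 kept their side of the threshold, 1050 fell short of it and 13 passed it. Larger shares fell short in some other alternatives. With only the groups compared 240 kept their side and 124 fell short, and with the per-gene library 355 and 148. The largest exon piece gave 410 and 85, and no filter 431 and 79. With DESeq2 486 kept their side, 0 fell short and 17 passed. Direction was compared only for genes called in the main fit or in the alternative, so uncalled genes may have turned. For lists, 4 of 92 calls held with an estimated correlation, 34 with fry and 74 without high-fat females 4 and 5. The interaction can show little of small changes: a simulated fold of 1.5 was recovered in 26.9% of genes there.

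Counts of called genes moved by over 1.5 times as follows, and for the alternatives the cause was not tested unless stated. For diet in females (457) DESeq2 called 1002, no filter 195, only the groups compared 21, without high-fat females 4 and 5 906, the GC covariate 943, the largest exon piece 254 and the per-gene library 71. For diet in males (138) the counts in that order were 254, 84, 572, 474, 431, 90 and 80, and a replicate block gave 85. For the diet by sex interaction (0) DESeq2 called 60 and the largest exon piece 1. For sex on chow (582) DESeq2 called 907, no filter 351, only the groups compared 1538, without high-fat females 4 and 5 1916, the GC covariate 1805 and the largest exon piece 359. For sex on high-fat diet (1866) no filter gave 1108, only the groups compared 547, the GC covariate 1231 and the per-gene library 613. For diet averaged over sexes (530) DESeq2 called 849, no filter 351, without high-fat females 4 and 5 1549, the GC covariate 1491 and the per-gene library 261. Without a filter more genes are tested, and with only the groups compared the libraries of those groups alone set the spread. In that setting the count fell for diet in females and sex on high-fat diet, which include the high-fat females. It rose for diet in males and sex on chow, which do not. Fewer libraries alone therefore do not account for the moves. The share of calls that were higher in diet in females went from 65.9% to 49.6% without high-fat females 4 and 5 and 47.0% with the GC covariate.

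The overlap of diet calls between sexes (56 genes) was 100 with DESeq2, 30 without a filter, 11 with only the groups compared, 152 without high-fat females 4 and 5, 145 with the GC covariate, 23 with the per-gene library and 191 at an unadjusted p under 0.01 in both. With each library left out in turn, it ran from 20 to 65, and called genes ran from 219 to 909 for diet in females, 42 to 198 for diet in males, 0 to 5 for the interaction, 259 to 861 for sex on chow, 1096 to 3447 for sex on high-fat diet and 356 to 655 for diet averaged over sexes. Called lists, of which the interaction had 8 without chow male 1 or high-fat male 2, ran from 13 to 23, 17 to 22, 8 to 16, 6 to 11, 12 to 16 and 19 to 25 in the same order.

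The number of called lists fell with an estimated correlation to 0 for diet in females, 1 for diet in males, 0 for the interaction, 1 for sex on chow, 0 for sex on high-fat diet and 2 for the average, and with fry to 11 for diet in females, 2 for diet in males, 0 for the interaction and 4 for sex on chow. For the interaction (13 lists) the stricter filter gave 7, without high-fat females 4 and 5 25 and the GC covariate 24; sex on chow (8) gave 14 without a filter, and sex on high-fat diet (13) gave 24 without high-fat females 4 and 5 and 28 with the GC covariate. Lists that turned direction did so without high-fat females 4 and 5 and with the GC covariate: uncoupling and antioxidant defence, diet in females (adjusted p = 0.301 and 0.214), autophagy and lysosome genes, diet in females (adjusted p = 0.0987 and 0.0433), glucose uptake and glycolysis, diet by sex interaction (adjusted p = 0.690 and 0.0755), cytosolic ribosomal proteins, diet by sex interaction (adjusted p = 4.81e-05 and 8.31e-12), and glucose uptake and glycolysis, sex on high-fat diet (adjusted p = 0.804 and 0.129). Autophagy and lysosome genes, sex on high-fat diet, turned with the GC covariate (adjusted p = 0.332), and cytosolic ribosomal proteins, diet in males, with the per-gene library (adjusted p = 0.480); the cause was not tested.

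Little sign of pairing by replicate number was seen: of 27 same-numbered pairs, 2 had a correlation of deviations over 0.1, with a range of -0.067 to 0.161. Libraries of different number were not compared in this way, so a weak pairing is not excluded. A replicate block gave 340 genes for diet in females, 85 for diet in males, 0 for the interaction, 460 for sex on chow, 1883 for sex on high-fat diet, 465 for the average and 41 for the overlap. The planned transcript-length offset was not run, because the files hold no transcript estimates.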

Other observations

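All values in this part were picked after the data had been seen, except the gene lists, which were fixed before. In high-fat males several further lists moved by camera with Benjamini-Hochberg adjustment. Glucocorticoid-responsive genes had a median change of 0.18, with 2 of 20 higher (adjusted p = 6.5e-08; adjusted p = 0.203 with an estimated correlation), and mitochondrially encoded genes of 0.25 with none of 13 called (adjusted p = 6.35e-05; adjusted p = 0.387 with an estimated correlation). In the fit without high-fat females 4 and 5 there were 5 of these 13 called higher (list by camera adjusted p = 1.01e-07; adjusted p = 0.286 with an estimated correlation). Macrophage markers had a median of -0.22 (adjusted p = 0.000307; adjusted p = 0.352 with an estimated correlation) and adult sarcomere genes of -0.11 (adjusted p = 0.0003; adjusted p = 0.459 with an estimated correlation). In high-fat females Slc4a1, the anion exchanger of red blood cells, rose by 1.92 ± 0.38 (SE; edgeR adjusted p = 0.0133) and lay above every chow female in 4 of 5 libraries. Between the sexes on chow, ribosomal protein genes had a median of 0.16 with none of 81 called (adjusted p = 1.6e-09; adjusted p = 0.967 with an estimated correlation). In the fit without high-fat females 4 and 5 there were 21 of 81 called higher (list by camera adjusted p = 2.17e-13; adjusted p = 0.966 with an estimated correlation).

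Single libraries stood apart in some gene lists. In chow female 3 the median of interferon-stimulated genes lay 1.02 log2 units above the mean of the other chow females and that of genes of MHC class II antigen presentation 1.44 above, with Iigp1 at 117 CPM and Irgm2 at 93.3 CPM, against 20.4 to 27.6 and 11.9 to 15.7 CPM in the other chow females. Some immune cell markers lay higher in the same library, T and NK cell markers by 1.10, neutrophil markers by 0.67 and macrophage markers by 0.32. B and plasma cell markers did not, at -0.073. A change in cell number is therefore not separated from one in gene activity. In chow male 2 neutrophil markers lay 1.67 above the mean of the other chow males, inflammatory cytokines and adhesion genes 0.71 above and immediate early genes 0.56 above, and Thbs1 stood at 146 CPM, against 8.79 to 18.5 CPM in the other chow males. Cyp26b1, which breaks down retinoic acid, stood at 71.4 CPM in chow male 3 and at 7.78 CPM or less in the other libraries compared. Xlr4a stood at 20.7 CPM in high-fat male 3 and at 1.66 to 2.61 CPM in the other high-fat males.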
